A study of Ruditapes philippinarum with 16 samples.

How the data were processed

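Total RNA from clam haemocytes was labelled with Cy3 and hybridised to 16 Agilent one-colour arrays, per the labels' protocols. The 4 wild arrays and the 12 laboratory arrays formed 8 groups: 4 of 3 pools and 4 of 1 control array. Pools of 1 group are separate biological replicates per the series design, and each control array is a pool of 3 replicates.

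The authors extracted spot intensity values with Agilent Feature Extraction, version 9.5 per the submitters' processing notes and 9.5.1.1 per the file headers. The deposited intensity columns used here were the processed signal, already background-corrected by that software, and the mean and background median signals. The deposited series value table holds intensity values on a linear scale. Its columns ranked probes as the processed signal did (Spearman correlation 1 on all arrays), had medians of 388, and were blank where a probe was not well above background or was an outlier. The equal medians show a scaling between arrays, whose method is not given in the sources used here.

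The array held 15151 spots, of which 536 were control spots and were left out. The 14615 probes had 13764 distinct sequences of 52 to 60 bases from 11052 contigs, all described as Unknown in the files. The gene table of the clam genome annotation holds no sequences and none of the contig names, so 0 probes were assigned to a gene, and the gene lists fixed before the data were examined were not tested. Probe sequences are given only for probes well above background on all 16 arrays, and different probes of a contig were tested separately. The 11 probe spots marked as outliers by the software were left out, and saturated spots (9) were kept.

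Log2 of the processed signal minus the 75th percentile of each array was used. Probes well above background on at least 3 of 16 arrays (12340) were tested with limma (version 3.58.1, R 4.3.3), with lmFit, contrasts.fit and eBayes, two-sided, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. All 16 arrays in 8 groups entered the fit, except that the challenge effect over all times used the 12 laboratory arrays with time as a term. With 1 control array, that array was assumed to vary like the groups of 3, which gave 8 residual degrees of freedom and a prior of 3.03. The effect of challenge by time was tested with a moderated F test.

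The named probes were set by a rule fixed before the data were examined: because no probe had a gene, up to 2 that rose and 2 that fell most among those past the threshold with all arrays on 1 side, or those with the smallest p where none passed. Alternatives fixed at the same time were normexp background correction (offset 50), quantile normalization, median scaling, the series value table, other filters on dim probes, outlier spots kept, other sets of arrays and controls, a size rule with no test, pool letter as a block, and leaving out each array. Those chosen after seeing the data were leaving out spots in dim patches, means per contig, and leaving out the 2 low-signal arrays. A spot was in a dim patch where the median deviation of probes within 4 rows and 2 columns (at least 8 probes) from their medians over 16 arrays was under -0.5 relative to the array.

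The functions were tested on simulated data with the real means and spreads, on 12340 probes, of which 67 were changed 2-fold, 67 4-fold and 66 8-fold. At 8-fold, 68.2% were recovered in the wild comparison, 68.2% at 10 h and at 24 h, 72.7% at 8 d, 98.5% over all times, and 84.8%, 89.4% and 83.3% in the comparisons of 24 h with 10 h, 8 d with 10 h and 8 d with 24 h. The test of the challenge effect by time recovered 27.3% and that of the wild against the challenge effect 50.0%. Between 2 and 7 false calls were made in each. At 2-fold, 1.49% were recovered in the wild comparison. The simulated noise was normal and independent between probes, and all changed probes were changed in the same run. The shares hold for that setting and may overstate recovery where few probes change or the noise differs. Slide could not be fitted as a block, since each slide holds whole groups. All 16 arrays were scanned on 1 day.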

Results

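Haemocytes, the circulating immune cells of bivalves, were profiled in the Manila clam Ruditapes philippinarum in relation to Perkinsus olseni, a protozoan parasite of clams. The design addressed 2 settings. In the wild-infection experiment, clams came from a bed where the parasite occurs, and 3 pools of infected clams (A, B and C) were set against 1 control array. In the laboratory challenge, clams from an infection-free bed were immersed with or without zoospores, the swimming stage of the parasite, and were not fed. Haemocytes were taken at 10 h, 24 h and 8 d, with 3 challenged pools and 1 control array at each time. Each control array carried a pool of 3 control replicates. RNA was measured on 16 one-colour arrays with 14615 clam probes. Between 9981 and 11980 probes were well above background on an array, and 12340 probes that were so on at least 3 arrays were tested. The 75th percentile of signal lay between 482 and 1561, with the lowest values on the 24 h challenged pool A (482) and the 10 h challenged pool B (516) and at least 942 elsewhere. All values are log2 signals relative to the 75th percentile of their array. The number of arrays limits the precision.

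The probes carry contig names only, so transcripts are given by probe name, and no probe was assigned to a gene. Arrays of the same group correlated at r = 0.955 to 0.983 across probes, wild with laboratory arrays at 0.931 to 0.968, and laboratory arrays with each other at 0.9335 to 0.9851. The first principal component, with 24.6% of the variance, placed the 4 wild arrays between -62.3 and -49.9 and the 12 laboratory arrays between -13.7 and 82.1. The wild arrays and the 10 h set shared 1 slide, and the 24 h and 8 d sets the other.

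**Figure D1:**
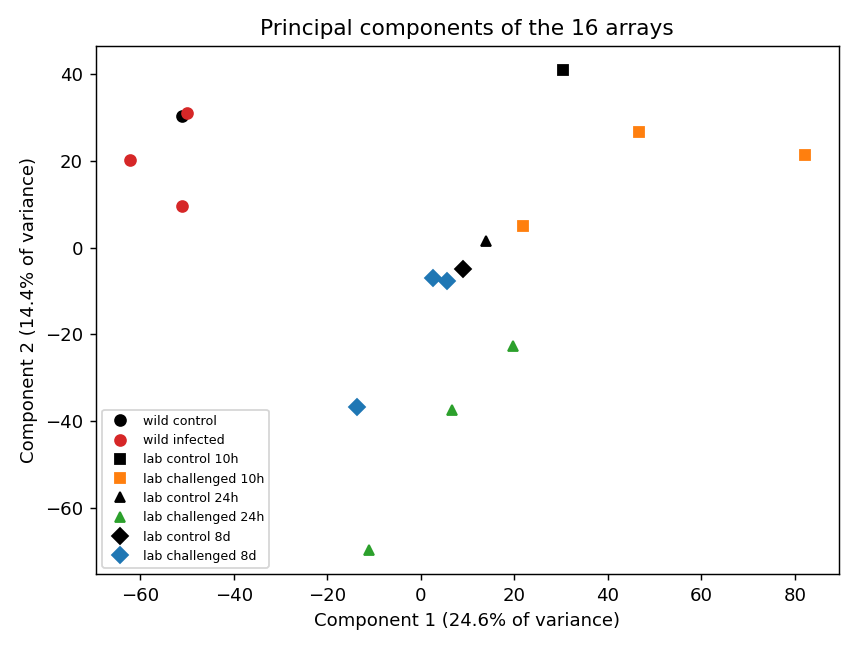
Each point is 1 array, placed by its scores on the first (horizontal, 24.6% of variance) and second (vertical, 14.4%) principal components of log2 signal. Shape gives the experiment and time, black the controls and colour the infected or challenged pools. The 4 wild arrays lie at the left, from -62.3 to -49.9 on component 1.

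Wild-infected clams were compared with the wild control to ask which transcripts differ in haemocytes of naturally infected clams. The 26 probes that passed were all higher in the infected pools, by 1.63 to 7.71 on the log2 scale, and none was lower. With no filter on dim probes 23 were higher and 7 lower, and with normexp 140 and 2. The largest difference was at Rphi_rep_c42017.0 (probe sequence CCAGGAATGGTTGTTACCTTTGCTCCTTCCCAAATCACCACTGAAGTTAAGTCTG), at 5.77 ± 0.10 (SD, n = 3) in infected pools and -1.94 in the control, a log2 fold change of 7.71 (SE 0.30, limma adjusted p = 4.72e-07). Rphi_rep_c35033reverse.0 (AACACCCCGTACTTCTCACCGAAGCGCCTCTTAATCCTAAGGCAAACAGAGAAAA) stood at 7.09 ± 0.24 (SD, n = 3) against -0.46, a log2 fold change of 7.55 (SE 0.32, limma adjusted p = 5.69e-07). All 26 probes lay in an area of the control array (rows 87 to 108, columns 37 to 42) where its spots were dim. At these probes the control differed from the other 15 arrays by a median of -3.63 on the log2 scale. With dim patches left out, an alternative chosen after seeing the data, 0 of 11600 probes passed in limma, and 115 had an unadjusted p under 0.05, 48 higher and 67 lower.

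Outside the patch, the probes with the smallest p were named after their values were seen, and none passed. Higher in infected pools were comp216029_c0_seq1.0 (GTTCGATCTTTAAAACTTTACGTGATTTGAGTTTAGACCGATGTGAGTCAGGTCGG), with a log2 fold change of 2.67 (SE 0.47), and ruditapes_c14607.0, at -4.16 ± 0.49 (SD, n = 3) in infected pools and not well above background in the control. Lower were comp368626_c1_seq1.0 (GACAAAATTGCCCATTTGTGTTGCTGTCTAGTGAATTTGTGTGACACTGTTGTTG), with -3.38 (SE 0.61), and Rphi_rep_c41934.0, with -2.69 (SE 0.64). With dim patches left out each had an adjusted p of 1.00 in limma, and with all spots kept comp216029_c0_seq1.0 had an adjusted p of 0.0546. The single control lay outside the range of all other arrays at comp216029_c0_seq1.0 (-3.30 against -0.91 to 3.39) and comp368626_c1_seq1.0 (0.04 against -4.69 to -2.54). It also did so at ruditapes_c14607.0 (-6.72 against -4.99 to -2.97). At Rphi_rep_c41934.0 it lay within their range (-1.97 against -5.25 to -1.53). By size alone, 47 probes outside the patch were at least 2-fold above the control in all 3 infected pools and 61 were at least 2-fold below it.

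**Figure D2:**
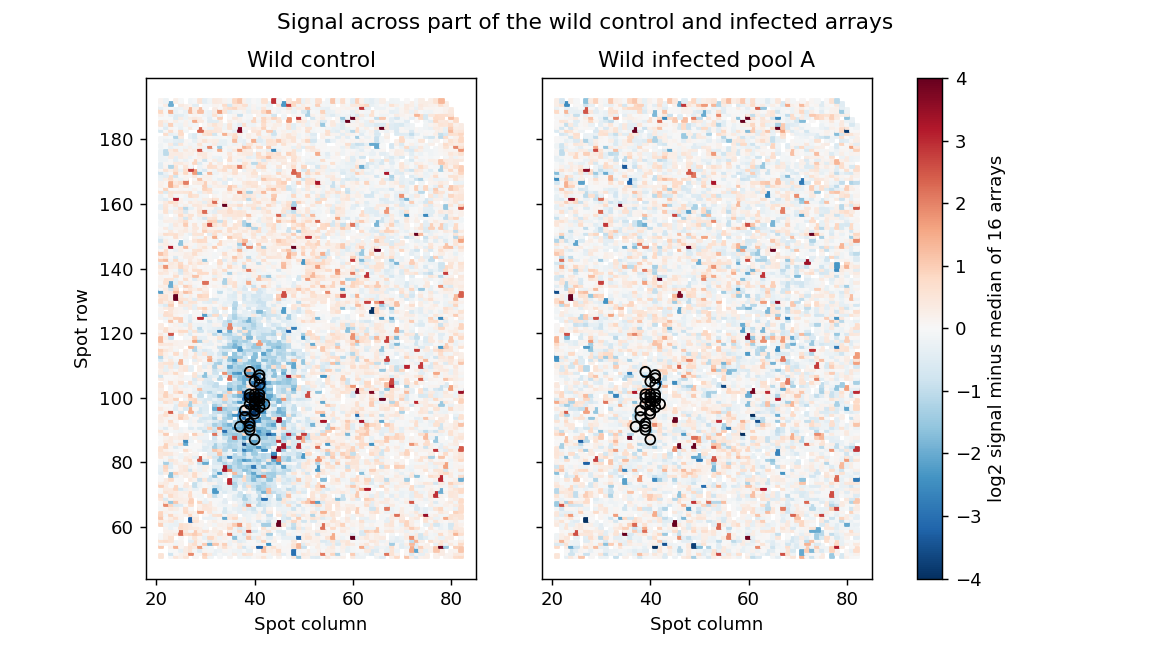
Spots of part of the wild control array (left) and of the array of infected pool A (right), by spot column (horizontal) and spot row (vertical). Colour gives the log2 signal minus the median of the 16 arrays, and circles mark the 26 probes that passed. All circles fall in the dim area of the control.

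At 10 h after challenge, 2 probes passed, both from the contig Contig6626 and both lower in challenged clams. Contig6626.0 stood at -7.85 ± 0.75 (SD, n = 3) in the challenged pools, where it was not well above background, and at -1.92 in the control. It was therefore at least 13.2-fold lower (limma adjusted p = 0.0497). Contig6626.1 stood at -7.53 ± 0.41 (SD, n = 3) and -1.99 and was at least 12.5-fold lower (limma adjusted p = 0.0234). Such bounds set the brighter group's mean against that of the dimmer group, after raising each of its arrays to the lowest signal that was well above background on that array. In the later controls Contig6626.0 was -7.61 at 24 h and -8.53 at 8 d, close to the challenged clams, while the wild arrays ranged from -2.46 to -1.20. No probe was higher. Without challenged pool A or pool C 0 probes passed. The 2 calls were also lost with median scaling or normexp background correction, which each gave 0.

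At 24 h, no probe passed in limma (smallest adjusted p = 1.00), and 198 had an unadjusted p under 0.05, 83 higher and 115 lower. The probes with the smallest p, named without passing, were lower for comp368108_c0_seq2.0 and Contig839.0. The first was at least 3.30-fold lower, at -3.71 in the control and not well above background in the challenged pools. Contig839.0 (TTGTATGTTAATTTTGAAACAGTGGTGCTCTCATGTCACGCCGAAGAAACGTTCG) stood at -3.95 ± 0.66 (SD, n = 3) against -0.54, a log2 fold change of -3.41 (SE 0.66). With the 3 laboratory controls as 1 group it had -4.29 (limma adjusted p = 0.012), and over the alternatives its adjusted p ranged from 0.00329 to 1.00. The controls stood at 0.94 at 10 h, -0.54 at 24 h and 0.62 at 8 d. Taking them as 1 group therefore adds their differences with time and slide to the challenge effect. On the other side, Rphi_c18408reverse.0 was at least 1.31-fold higher and ruditapes2_lrc6041.0 at least 1.63-fold higher, each measured in 2 of 3 challenged pools and not well above background in the control. Without challenged pool C 1 probe passed.

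At 8 d, no probe passed either (smallest adjusted p = 0.0735), and 216 had an unadjusted p under 0.05, 58 higher and 158 lower. The smallest p belonged to comp216029_c0_seq1.0, at -0.35 ± 0.40 (SD, n = 3) in challenged pools and 3.39 in the control, a log2 fold change of -3.74 (SE 0.47, limma adjusted p = 0.0735). The other laboratory controls had -0.83 and 0.04, and the wild control -3.30. Its adjusted p ranged from 6.86e-05 to 1.00 over the alternatives. It was under 0.05 with normexp, quantile normalization, the series values, no filter on dim probes, only probes well above background on all arrays, outlier spots kept and the log ratio to the control tested against 0. comp282034_c0_seq1.1 followed with -6.64 (SE 0.89, limma adjusted p = 0.0735), at 0.67 in the control. The other laboratory controls had -5.54 and -5.88, and the wild control -5.94. This probe was well above background in 1 challenged pool, so the size of its difference is uncertain, and normexp gave -4.50. Its adjusted p ranged from 6.86e-05 to 1.00 as well, and was under 0.05 with normexp, quantile normalization, no filter, outlier spots kept, the log ratio and without pool A. The other probe of its contig had -2.62. Among probes on the higher side, Contig9977.0 was at least 4.55-fold higher than its control, and Contig10742reverse.0 (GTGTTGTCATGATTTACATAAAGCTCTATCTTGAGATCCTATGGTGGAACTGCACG) had 1.34 (SE 0.34), neither passing. Without challenged pool A 1 probe passed, 6 passed with normexp and 32 with no filter on dim probes, all lower.

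Across the 3 times, with time as an additive term, no probe passed, and the smallest p values belonged to probes with lower signal in challenged clams. Rphi_rep_c33494reverse.0 stood at 1.02 ± 1.68 (SD, n = 9) in challenged pools and 5.53 ± 0.82 (SD, n = 3) in controls, a log2 fold change of -4.52 (SE 0.74). The second probe of that contig had -4.01. Rphi_rep_c13998.0 stood at 1.95 ± 1.60 (SD, n = 9) and 6.03 ± 1.12 (SD, n = 3), a log2 fold change of -4.08 (SE 0.73). Neither passed (limma adjusted p = 0.54 for each). On the higher side, the smallest p belonged to ruditapes_c18442.0, with 1.08 (SE 0.24) and well above background in 1 of 3 controls, and Rphi_c21477.0, at least 1.05-fold higher (limma adjusted p = 0.731 for each). The count of 0 came from limma, and 605 probes had an unadjusted p under 0.05, 203 higher and 402 lower. Without the 10 h control array 1 probe passed, lower in challenged clams.

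**Figure D3:**
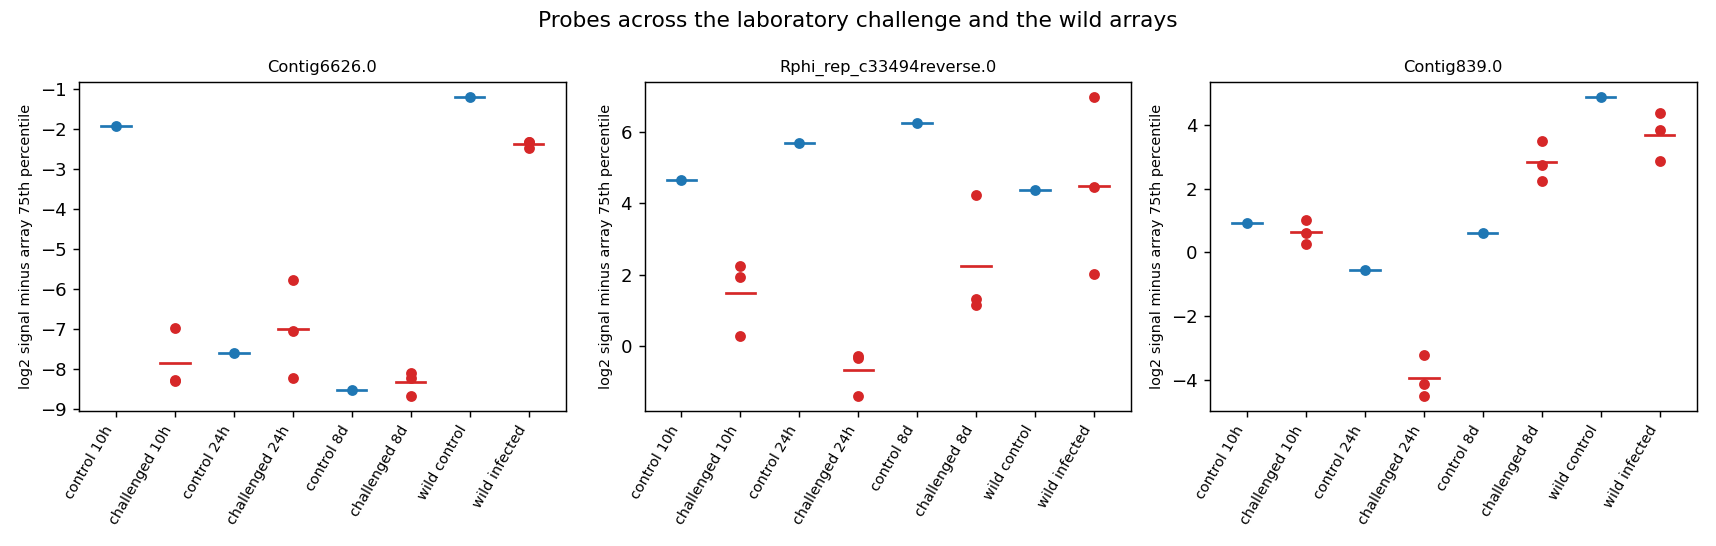
Log2 signal relative to the array's 75th percentile (vertical) of 3 probes in the 8 groups (horizontal). Points are single arrays (blue controls, red infected or challenged) and lines are group means. Contig6626.0 was high in the 10 h control and the wild arrays, Rphi_rep_c33494reverse.0 was lower in all 9 challenged pools than in the control of their time, and Contig839.0 was lowest in challenged clams at 24 h.

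By the size rule alone, with no test, more probes lay below the control than above it in challenged clams. At 10 h, 94 probes were at least 2-fold higher in all 3 pools and 233 at least 2-fold lower. The counts were 87 and 209 at 24 h and 60 and 252 at 8 d. The same rule with another array in the control's role gave up to 1302 probes higher at 10 h (pool B) and 1312 at 24 h (pool A), the arrays with the lowest signal. With 10 h pool C in that role, 92 were higher and 200 lower, so the excess of lower probes at 10 h was not particular to the control. At 24 h and 8 d no challenged pool in that role gave more lower than higher probes. A control array is a pool of 3 replicates, so it is not exchangeable with a challenged pool in this count. Whether pooling of the controls gives such an excess of lower probes was not tested.

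**Figure D4:**
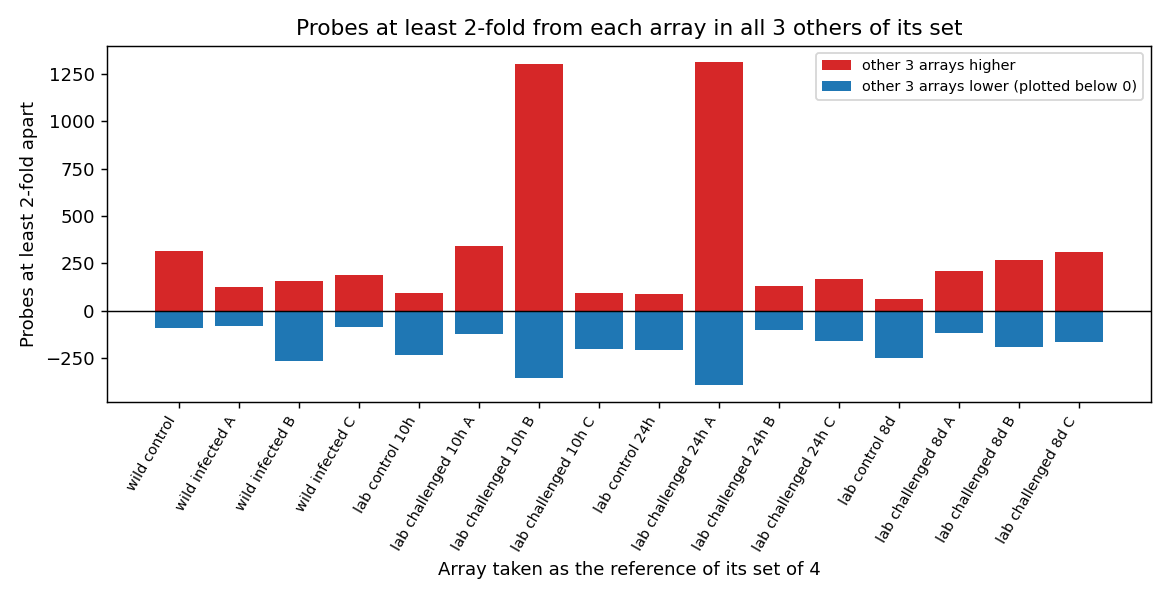
Number of probes (vertical) at least 2-fold higher (red, above 0) or lower (blue, plotted below 0) in the 3 other arrays of a set than in the array named on the horizontal axis. The 10 h pool B and 24 h pool A arrays stand out with 1302 and 1312 probes, above all 4 control arrays.

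Among challenged clams, 19 probes differed between 24 h and 10 h, 7 higher and 12 lower at 24 h. Contig839.0 was lower at 24 h by -4.58 (SE 0.47, limma adjusted p = 0.0109), from 0.63 ± 0.37 to -3.95 ± 0.66 (SD, n = 3 each). ruditapes_s33464.0 (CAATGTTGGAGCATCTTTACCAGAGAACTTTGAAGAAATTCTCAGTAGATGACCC) was lower by -2.67 (SE 0.34, limma adjusted p = 0.0159). Higher at 24 h were comp394473_c0_seq1reverse.0, at least 3.20-fold (limma adjusted p = 0.0384), and comp384515_c2_seq7reverse.1, at least 1.82-fold (limma adjusted p = 0.0218), each measured in 2 of 3 pools at 24 h and in none at 10 h. The other probes of these contigs had log2 fold changes of 0.805 and 0.49 and did not pass. With normexp the named probes had 0.53 and 0.33 and did not pass either. Between the control arrays of these times the 12 lower probes were also lower, by a median of -1.54 against -2.40 in challenged clams. The 7 higher probes were also higher there, by a median of 0.36 against 1.54. The 2 times lay on different slides, so slide and time cannot be told apart. The count was 0 without 10 h pool A or pool B, 2 without 24 h pool A or pool C, 7 without 24 h pool B and 1 in a fit of the 9 challenged arrays. The split of higher to lower was 2 to 11 with normexp, 3 to 11 with median scaling, 19 to 20 with quantile normalization and 0 to 9 with the series values.

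Between 8 d and 10 h, 51 probes differed, 47 higher and 4 lower at 8 d. comp372908_c0_seq8reverse.0 was at least 5.50-fold higher (limma adjusted p = 0.00608), at -3.18 ± 0.86 (SD, n = 3) at 8 d and not well above background at 10 h. The other probe of its contig had a log2 fold change of 1.45 and did not pass. With normexp comp372908_c0_seq8reverse.0 had 1.04 and did not pass. comp606394_c0_seq1.0 stood at -2.62 ± 1.07 (SD, n = 3) at 8 d (limma adjusted p = 0.0391) and was well above background in 1 of 3 pools at 10 h, so the size of its difference is uncertain. Its log2 fold change was 4.21 by the processed signal, 1.42 with normexp and 2.54 with the series values, and its adjusted p ranged from 0.0243 to 0.251 over the alternatives. Rphi_rep_c8044reverse.0 was at least 3.05-fold lower (limma adjusted p = 0.0408) and Rphi_c17970.1 at least 1.75-fold lower (limma adjusted p = 0.0466), both not well above background at 8 d. Of the 47 higher probes, 45 were also higher in the 8 d control than in the 10 h control, by a median of 1.22. All 4 lower probes were also lower in the 8 d control, by a median of -2.27 against -2.34 in challenged clams. Slide and time cannot be told apart here either. The count fell to 13, 31 and 9 without 10 h pool A, B or C, to 4, 3 and 25 without 8 d pool A, B or C, and to 0 in a fit of the 9 challenged arrays, and the split was 7 to 2 with median scaling. The count was 1 with normexp and 1 with the series values, and 123 (100 higher and 23 lower) among probes well above background on all arrays. Without both low-signal arrays, an alternative chosen after seeing the data, it was 227.

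Between 8 d and 24 h, which shared a slide, 43 probes differed, 28 higher and 15 lower at 8 d. Contig839.0 rose most, by 6.77 (SE 0.47, limma adjusted p = 0.000196), from -3.95 ± 0.66 to 2.83 ± 0.64 (SD, n = 3 each). Rphi_rep_c49047.0 rose by 5.09 (SE 0.64, limma adjusted p = 0.00451) and was well above background in 2 of 3 pools at 24 h. Of the 28 probes higher at 8 d, 12 had also been lower at 24 h than at 10 h past the threshold. All 28 were higher in the 8 d control than in the 24 h control as well, by a median of 1.01 against 3.10 in challenged clams. Rphi_rep_c2593reverse.0 was at least 8.80-fold lower at 8 d (limma adjusted p = 0.0269) and Rphi_rep_c8044reverse.0 at least 7.29-fold lower (limma adjusted p = 0.00442), neither well above background then. From the 24 h to the 8 d control, Rphi_rep_c8044reverse.0 also fell, from -2.76 to -8.34. Rphi_rep_c2593reverse.0 went from -5.48 to -4.53 between these controls. The 15 probes lower at 8 d had a median of -3.54 in challenged clams and of 0.94 between the control arrays, which were lower for 5 of the 15. The count was 79 without 24 h pool A and 25, 28, 25 and 23 without 24 h pool B, 24 h pool C, 8 d pool A or 8 d pool C, and normexp gave 28 higher and 67 lower, quantile normalization 29 and 9, and the series values 20 and 0.

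The effect of challenge was not shown to differ between times among the tested probes. In limma's moderated F test no probe passed (smallest adjusted p = 0.30), and 222 had an unadjusted p under 0.05. 1 probe passed without 24 h pool B or without 24 h pool C, 22 passed with no filter on dim probes, 3 with outlier spots kept and 2 with normexp. Contig839.0 had challenge effects of -3.41 at 24 h and 2.20 at 8 d, which therefore were not shown to differ over all probes. Within the slide that held 24 h and 8 d, the difference between those 2 effects gave 0 probes, with 188 at an unadjusted p under 0.05.

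The wild effect exceeded the mean challenge effect at 22 probes, with none on the other side. With no filter on dim probes 20 were higher and 4 lower, and with normexp 66 and 2. Rphi_rep_c42017.0 and Rphi_rep_c35033reverse.0 led the wild comparison and differed here by 7.68 and 7.84. Of the 22 probes, 21 lay in the dim patch of the wild control. The other, named after its values were seen, was comp216029_c0_seq1.0, with a difference of 3.77 (limma adjusted p = 0.0191). Its single control arrays stood at -3.30 in the wild and 3.39 at 8 d. In limma, with dim patches left out 0 of 11597 passed, with 193 at an unadjusted p under 0.05. Against the 10 h effect alone, measured on the same slide, 14 probes passed, all in the patch. The count was 14 without infected pool B and 41 without 10 h pool B. Across probes outside dim patches, the wild effect correlated with the challenge effects at r = -0.00509 at 10 h, 0.0778 at 24 h and 0.00419 at 8 d, while the 3 challenge effects correlated with each other at 0.237, 0.303 and 0.215. Probes are not independent replicates.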

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

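The tests of explanations in this part were chosen after the results were seen, while leaving out single arrays and the test of the wild against the challenge effect were planned. The wild effect differed from the mean challenge effect at 22 probes in a test of that difference, with Rphi_rep_c42017.0 at 7.68 and Rphi_rep_c35033reverse.0 at 7.84 on the log2 scale. Of the 22, 21 lay in the dim patch of the wild control, and comp216029_c0_seq1.0 (3.77) lay outside it. The 26 probes higher in wild-infected clams all lay in dim patches of the wild control array, which held 740 of the 12340 tested probes. For 12 of them another probe of the same contig or the same sequence lay outside the patch, and these 13 probes had a median log2 fold change of -0.19 (range -0.54 to 0.71), against 3.40 for their partners. For these 12, that argues against more transcript in infected clams, and it is consistent with a local loss of signal on the control array.

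The 3 challenge effects agreed across probes, with a mean r of 0.247 although no array was shared, and of 0.0997 without the Rphi probes. Of the 64 ways to take 1 array per time as the control, 1 gave a mean r as high, the real one, and the highest other was 0.22. This argues against chance on the log scale but cannot exclude it. A control array is a pool of 3 replicates, so it is not exchangeable with a challenged pool. The wild effect, whose control had the same place on the slide, correlated with the mean challenge effect at 0.032 outside the dim patch. It rests on 1 control array, which is also a pool of 3 replicates. Probes of 1 contig agreed less in the wild effect (r = 0.326, dim patch included) than in the challenge effects (0.766, 0.656 and 0.720). The low value therefore cannot separate place from pooling, and the place of the controls stays open. Pooling of 3 replicates in each control stays open: with challenged arrays averaged before the log, 3 of the 64 choices gave a mean r as high as the real 0.197, with a highest other of 0.286. An effect of the challenge itself was not separately tested and stays open.

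Of the probes higher at 8 d than at 24 h in challenged clams, 26 of 28 still passed without the low-signal 24 h pool A, which argues against that array as the cause. Most of the 28 fell into 1 set by their correlation over the laboratory arrays, so they are not 28 separate observations. The control arrays changed the same way at all 28 probes, by a median of 1.01 against 3.10, so a change with time shared by unchallenged clams may account for part of it, and the single controls keep this open. An effect of the parasite was not separately tested.

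For the time comparisons the 6 arrays allow 10 splits, too few for a share under 0.05. The real split gave 19, 51 and 43 probes for 24 h against 10 h, 8 d against 10 h and 8 d against 24 h, each reached by 1 of the 10, and the highest others were 2, 2 and 3. Over all times the real choice gave 0 probes, a count that all 64 choices reach by construction, so this says nothing about chance. The highest other choice gave 15 probes.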

How the results depend on the processing

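The alternatives with dim patches left out, with means per contig and without low-signal arrays were chosen after seeing the data. In the order wild, 10 h, 24 h and 8 d against control, the counts were 26, 2, 0 and 0. Over all times the count stayed at 0 under the 12 settings tried, and at 0 to 1 with 1 array left out. Named probes kept their direction in every setting that gave them a value. They were on the same side of the threshold in 332, no longer past it in 86 and newly past it in 20. The named probes of the wild comparison had no value with dim patches left out. Means per contig and the size rule gave no value for any named probe. The cause of the changes below was not tested, except where fewer arrays or probes entered.

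With normexp, the counts were 142 for wild, 0 at 10 h and 6 at 8 d, 1 for 8 d against 10 h, 95 for 8 d against 24 h, 2 for the challenge effect by time and 68 for the wild against the challenge effect. With quantile normalization they were 55 for wild, 4 at 10 h, 2 at 8 d, 39 for 24 h against 10 h and 26 for 8 d against 10 h. With median scaling they were 0 at 10 h and 9 for 8 d against 10 h. With the series values they were 0 at 10 h, 1 at 8 d, 9 for 24 h against 10 h, 1 for 8 d against 10 h and 20 for 8 d against 24 h. The median of all probes shifted to 0.16 at 10 h with median scaling and with normexp, to 0.12 at 24 h with normexp and to -0.25 in the wild comparison with normexp.

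With no filter on dim probes, the counts were 1 at 10 h, 32 at 8 d, 21 for 8 d against 10 h and 22 for the challenge effect by time. With probes well above background on all arrays they were 0 at 10 h, 1 at 8 d, 36 for 24 h against 10 h, 123 for 8 d against 10 h and 18 for 8 d against 24 h. With outlier spots kept they were 4 at 10 h, 1 at 24 h, 3 at 8 d and 3 for the challenge effect by time. The fold at named probes not well above background in the dimmer group could depend on the background correction. Contig6626.0 at 10 h had -5.93 by the processed signal and -2.22 with normexp. For 8 d against 10 h, comp372908_c0_seq8reverse.0 had 4.44 and 1.04.

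With only the arrays of each experiment, 7 passed for wild and 17 at 10 h. The log ratio tested against 0, which leaves out the spread of the control, gave 573, 1283, 138 and 193, and the size rule 404, 327, 296 and 312. With the 3 laboratory controls as 1 group the counts were 0 at 10 h and 1 at 24 h. Among the 9 challenged arrays, the counts for 24 h against 10 h and 8 d against 10 h were 1 and 0, and with pool letter as a replicate block 0 and 0, while 8 d against 24 h gave 29 and 36. Deviations of pools with the same letter correlated at -0.14 to 0.14.

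Dim patches held 740 tested spots on the wild control, 254 on 10 h challenged pool B, 47 on 24 h challenged pool A and 1 on 8 d challenged pool B. Without dim patches, the counts were 0 for wild, 1 at 10 h and 0 for the wild against the challenge effect. Means per contig gave 16, 1 at 10 h, 2 at 8 d and 13. Without low-signal arrays they were 1 for 24 h against 10 h, 227 for 8 d against 10 h and 90 for the wild against the challenge effect. With 1 array left out, the ranges were 18 to 23 for wild, 0 to 3 at 10 h, 0 to 1 at 24 h, 0 to 1 at 8 d, 0 to 26 for 24 h against 10 h, 3 to 31 for 8 d against 10 h, 23 to 79 for 8 d against 24 h, 0 to 1 for the challenge effect by time and 14 to 41 for the wild against the challenge effect. Slide as a block was not run, since it could not be estimated beside the groups, and the gene list alternatives were not run, since no probe had a gene.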

Other observations

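These sets were singled out after their values were seen. At 18 probes of 17 contigs the signal was at least 2-fold lower in all 9 challenged pools than in the control of their time, and at 0 probes at least 2-fold higher. All 18 carry the name prefix Rphi, which 3065 of the 12340 tested probes have. Clustering on their correlation with each other over the laboratory arrays put them into 2 sets. A set of 5 with brighter signal, including Rphi_rep_c47089.0 and Rphi_rep_c24335reverse.0, had control values of at least 2.91. Rphi_rep_c24335reverse.0 went from 4.29 to 1.77 at 10 h, from 5.71 to -0.24 at 24 h and from 6.45 to 2.63 at 8 d. The other 13, with dimmer signal, included Rphi_rep_c5898.0, at 0.14 in the control against -2.60 at 10 h, -1.72 against -5.89 at 24 h and -2.07 against -4.34 at 8 d. In the wild comparison none of the 18 passed in limma, with log2 fold changes from -2.60 (Rphi_c23106.0) to 0.47 (Rphi_rep_c24335reverse.0), a median of -0.33 and 11 of 18 below 0. Rphi_rep_c33494reverse.0 had pools on either side of the control and stood at 4.45, 6.97 and 2.01 in infected pools A, B and C and at 4.38 in the control. None passed over all times, and 2 of the 64 choices of 1 array per time gave as many such probes, with up to 25. Without Rphi probes the mean r of the 3 challenge effects was 0.0997, with a highest other of 0.08.

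Over all 14615 probes, a few pools carried sets of transcripts seen in no other array of their experiment. The 10 h control had 26 probes, from 23 contigs, at least 8-fold above every other laboratory array, with none of those well above background. Contig6626.0 and Contig6626.1, the 2 probes that passed at 10 h, were among them. For 17 of the 26 the contig had another probe, which in 16 cases was also at least 2-fold above. That other probe could itself be 1 of the 26, as for Contig6626.0 and Contig6626.1. The 16 cases are therefore not independent support. Of these 26 probes, 20 were well above background in the wild control, 19 in infected pool A, 23 in pool B and 4 in pool C. The 8 d control had 20 such probes, and 0 of them were well above background in any wild array. The 24 h control had 0, and each challenged pool had at most 1. The wild control had 17 such probes against the other wild arrays, and infected pools A, B and C had 4, 10 and 6.

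A hypothesis for the 13 dimmer probes is RNA of 1 other source in the haemolymph, which would keep them in 1 ratio. Their median pairwise correlation over the 12 laboratory arrays was 0.935. The set was formed by that same correlation, so a high value was given by construction and does not bear on the hypothesis. The probes were also chosen for a shared pattern, and shared regulation gives the same, so the source stays open. Per the labels, samples in which bacteria or gametes were seen by microscope had been discarded. No organism or cell type was assigned to any probe.

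Wild and laboratory clams differed beyond infection. Outside the dim patch, 39 probes were at least 2-fold higher in all 4 wild arrays than in all 12 laboratory arrays, and 2 were at least 2-fold lower. comp375442_c0_seq1.0 ranged from -2.21 to -1.21 in wild clams and was well above background on 1 laboratory array. Rphi_rep_c1371.0 ranged from -4.55 to 0.07 in wild and from 1.12 to 5.93 in laboratory clams. Across 11597 probes, the difference between the wild and 10 h controls correlated at r = 0.601 with that between wild-infected and 10 h challenged pools, which share a slide but no array. Per the labels the bed and the laboratory keeping differed between the experiments, and these were not separated.

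Of 236 contigs with probes in both orientations, 15 were well above background on all 16 arrays in both, 89 in 1 orientation and 132 in neither.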
